A study of Mus musculus with 8 samples.

How the data were processed

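The 3 progenitor populations were sorted by flow cytometry from the marrow of reporter mice, and their RNA was amplified by a whole-transcriptome kit made for small amounts of RNA and hybridised to Affymetrix arrays, per the labels' protocols. The labels name no sort markers, and do not say whether the samples of a group came from separate mice or sorts, so p-values measure the spread between these samples, which may be technical. Groups and replicate numbers came from the sample titles, which give 3, 3 and 2 arrays.

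The deposited values are probe set intensity values on a linear scale, summarised by robust multi-array average (RMA) in Affymetrix Expression Console, per the submitters' processing notes. The versions of these tools are not given in the sources used here. The authors' table holds 28853 probe sets for 8 arrays, and RMA gives no detection call, so that differences of genes near the floor are understated and a signal there is not proof of expression. The platform annotation names 1 gene for 21789 probe sets, several genes for 1621 and none that was used here for 5443; the last 2 kinds were left out. No symbol of a probe set with 1 gene needed updating through the RefSeq gene table of assembly GRCm38.p6, and no coordinates are given, since the build behind the array annotation is not given in the sources used here.

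The intensities were log2 transformed. Probe sets with at least 2 arrays above the array's own 40th percentile were kept, and each gene was represented by its probe set with the highest mean, which left 13356 genes. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with all 8 arrays in 1 fit so that the 3 groups share an estimate of the spread (5 residual degrees of freedom), and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. In the text "adjusted p" without further words is this value, or for a list the camera value adjusted over the 17 lists tested. For a family it is the camera value with an estimated correlation, adjusted over the 9 families, unless the preset one is named. A value after ± with a log2 difference is limma's standard error. The number of arrays limits the precision. The order from Zeb2hi to Zeb2low CDPs to pre-CD8 DCs in the 2 steps is an assumption, and the Zeb2low arrays enter both steps. All designs, gene lists, alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise.

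A total of 18 gene lists were written from textbook knowledge for this work: cDC1, cDC2 and plasmacytoid DC genes, DC transcription factors, antigen presentation, DC maturation and migration, stem and progenitor cells, mitosis, DNA replication, ribosome biogenesis, interferon-stimulated and immediate early genes, and markers of granulocytes, monocytes and macrophages, mast cells with basophils and eosinophils, erythroid cells with megakaryocytes, B cells, and T, NK and innate lymphoid cells. The transcription factors have no common direction and were only counted. The other 17 were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and with fry as alternatives; fry asks whether a list's genes move on balance 1 way and does not compare them with other genes. The named genes were 7 transcription factor genes in each comparison, the 6 largest differences in each direction past the test with non-overlapping arrays, up to 3 members of each list per direction past the test with the largest differences (or the 2 with the smallest p as values where none passed), and the 4 genes of each step pattern with the largest smaller step. Not all of them are printed.

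The fit was tested on simulated data, drawn from the means and spread of the 13356 genes, with 200 genes changed per comparison. The noise was independent between genes and arrays, so the false calls do not cover deviations that genes or paired arrays share. For Zeb2low against Zeb2hi CDPs 54 of 100 genes changed by 1 on the log2 scale and 89 of 100 changed by 2 were recovered, with 2 false calls. For pre-CD8 DCs against Zeb2low CDPs 46 and 89 of 100 were recovered, with 3 false calls. For pre-CD8 DCs against Zeb2hi CDPs 49 and 81 were recovered, with 5 false calls.

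Same-numbered arrays of Zeb2low and Zeb2hi CDPs deviated together from their group means (r = 0.478, 0.407 and 0.308 across genes for numbers 1, 2 and 3). The deviations of each Zeb2low array correlated best with those of the Zeb2hi array of its own number, so the numbers were taken to pair these arrays. The signals themselves of Zeb2low array 3 correlated less with Zeb2hi array 3 (r = 0.930) than with Zeb2hi array 1 (r = 0.936). The pairing comes from the values, since the labels give the numbers without a meaning. The fit with the replicate number as a block was planned over all arrays, and a fit over the 6 CDP arrays alone was added after seeing the data. Where a block changes the call of a printed list or named gene between Zeb2low and Zeb2hi CDPs, its value stands beside the result.

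The alternatives were no filter and a stricter filter at the 60th percentile, the compared groups alone in the fit, the replicate block, quantile normalization applied again, centring on array medians, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, all probe sets tested separately, a minimum of 2-fold, each array left out in turn, and both other list tests. Where several single arrays end the call of a gene printed with its value, the text names at least the one whose omission gives the highest adjusted p. Added after seeing the data were a score of 24 mature neutrophil genes as a covariate, a fit without both arrays at the ends of the second principal component, and the block over the CDP arrays. For the comparisons that share the Zeb2hi arrays, 100 simulations of unchanged groups gave the correlation and covariance that shared controls bring.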

Results

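Gene expression was measured on Affymetrix arrays in 3 populations of dendritic cell (DC) progenitors sorted from the bone marrow of mice that carry a Zeb2-GFP fusion reporter on 1 allele. Common DC progenitors (CDPs), the marrow cells that give rise to classical and plasmacytoid DCs, were taken as a Zeb2hi and a Zeb2low fraction with 3 arrays each. Pre-CD8 DCs, the committed precursors of the CD8a+ classical DC (cDC1), were measured on 2 arrays. The median log2 signal per array lay between 4.91 and 5.14. The Pearson correlation across genes between arrays of 1 group lay between 0.937 (the pre-CD8 DC arrays) and 0.989. Pre-CD8 DC array 2 correlated more with Zeb2low arrays 1 (0.942), 2 (0.955) and 3 (0.966) than with pre-CD8 DC array 1. Pre-CD8 DC array 1 correlated more with Zeb2low array 2 (0.958), but less with Zeb2low arrays 1 (0.883) and 3 (0.9295). The first principal component held 49.9% of the variance and set the 3 Zeb2hi arrays (scores of 37.2 to 46.9) apart from the 5 others (-41.0 to -14.8). The second held 24.5% and ran from Zeb2low array 1 (-45.1) to pre-CD8 DC array 1 (41.9).

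The Zeb2 transcript, which encodes the repressor that the reporter follows, was lower in Zeb2low CDPs (log2 signal 7.68 ± 0.18, SD, n = 3) than in Zeb2hi CDPs (9.27 ± 0.20, SD, n = 3). The log2 difference was -1.59 ± 0.18, adjusted p = 0.00196 (SE), a 3.02-fold lower signal. In pre-CD8 DCs the Zeb2 signal was 6.73 ± 0.28 (SD, n = 2), which put it 5.83-fold below Zeb2hi CDPs (-2.54 ± 0.20, adjusted p = 0.000177). Against Zeb2low CDPs the difference was not past the test (-0.95 ± 0.20, adjusted p = 0.0899). Id2, an inhibitor of E proteins needed for cDC1 development, rose 20.4-fold from Zeb2hi to Zeb2low CDPs (4.35 ± 0.28, adjusted p = 0.00018). It was also above Zeb2hi CDPs in pre-CD8 DCs (4.77 ± 0.31, adjusted p = 7.44e-05). Its difference between Zeb2low CDPs and pre-CD8 DCs did not pass (0.42 ± 0.31, adjusted p = 0.6). Nfil3, a transcription factor required for cDC1 progenitors, rose in Zeb2low CDPs (1.20 ± 0.20, adjusted p = 0.00824). It passed neither from Zeb2low CDPs to pre-CD8 DCs (-0.82 ± 0.23, adjusted p = 0.175) nor from Zeb2hi CDPs to pre-CD8 DCs (0.38 ± 0.23, adjusted p = 0.292).

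Batf3, which maintains the cDC1 programme, rose over Zeb2hi CDPs in Zeb2low CDPs (1.57 ± 0.20, adjusted p = 0.00323) and in pre-CD8 DCs (2.50 ± 0.23, adjusted p = 0.000391). Its difference between the latter groups did not pass (0.93 ± 0.23, adjusted p = 0.137). Zbtb46, a marker of the classical DC lineage, rose over Zeb2hi CDPs in Zeb2low CDPs (0.61 ± 0.14, adjusted p = 0.026) and in pre-CD8 DCs (1.19 ± 0.16, adjusted p = 0.00238), and did not pass between those groups (0.58 ± 0.16, adjusted p = 0.175). The first Zbtb46 call was lost without Zeb2hi array 2 (adjusted p = 0.108) or 3 (adjusted p = 0.104) and without Zeb2low array 2 (adjusted p = 0.0864) or 3 (adjusted p = 0.0816). It was also lost with the replicate number as a block over all arrays (adjusted p = 0.0606). Irf8, the factor that specifies cDC1s, had high signals in Zeb2hi CDPs (10.32), Zeb2low CDPs (9.72) and pre-CD8 DCs (10.37). No Irf8 difference passed, from Zeb2hi to Zeb2low CDPs (-0.59 ± 0.28, adjusted p = 0.173), from Zeb2low CDPs to pre-CD8 DCs (0.64 ± 0.31, adjusted p = 0.412) or from Zeb2hi CDPs to pre-CD8 DCs (0.05 ± 0.31, adjusted p = 0.931). The first passed without Zeb2hi array 1 (adjusted p = 0.0438) and with a block over the CDP arrays alone (adjusted p = 0.0213). Tcf4, the E protein that specifies plasmacytoid DCs, passed in none of the comparisons (-0.23 ± 0.21, adjusted p = 0.477, then -0.42 ± 0.24, adjusted p = 0.488 and -0.65 ± 0.24, adjusted p = 0.0986, in the same order). The probe sets of these 7 genes were 10482448 for Zeb2, 10399691 for Id2, 10409278 for Nfil3, 10352717 for Batf3, 10490682 for Zbtb46, 10576034 for Irf8 and 10456522 for Tcf4.

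**Figure D1:**
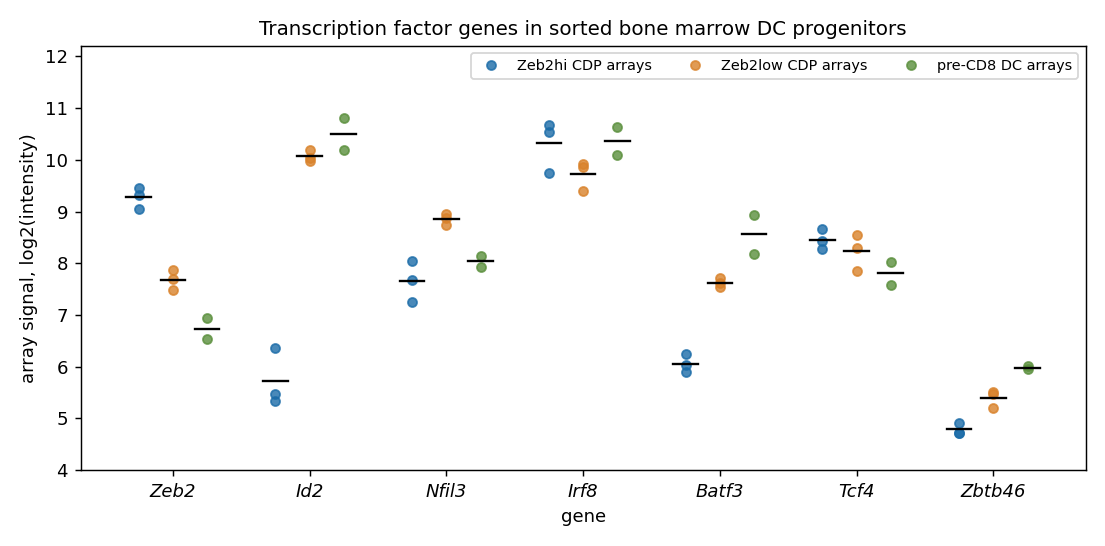
Log2 array signal (vertical axis) of 7 transcription factor genes (horizontal axis) in Zeb2hi CDPs (3 arrays), Zeb2low CDPs (3 arrays) and pre-CD8 DCs (2 arrays), with each dot 1 array and each bar the group mean. Zeb2 falls from a mean of 9.27 in Zeb2hi CDPs to 7.68 in Zeb2low CDPs, where Id2 stands at 10.07 against 5.73.

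MHC class II genes and cDC1 genes were among the largest single increases in Zeb2low CDPs over Zeb2hi CDPs (3 arrays each, log2 differences ± SE). The MHC class II gene H2-Aa rose 45.1-fold (5.50 ± 0.29, adjusted p = 9.85e-05), with its invariant chain Cd74 (4.88 ± 0.34, adjusted p = 0.000209) and H2-Ab1 (3.74 ± 0.25, adjusted p = 0.000192). The cDC1 genes Ifi205 (4.96 ± 0.17, adjusted p = 6.77e-06) and Tlr3, a sensor of double-stranded RNA (3.22 ± 0.14, adjusted p = 2.23e-05), rose too. Cd226, an adhesion receptor (4.42 ± 0.31, adjusted p = 0.000239), and the interferon-inducible Samd9l (4.18 ± 0.26, adjusted p = 0.00018) stood with H2-Aa, Ifi205, Cd74 and Id2 among the 6 largest increases. Cd226 and Tlr3 had low signals in Zeb2hi CDPs, where such arrays understate a difference. The largest decrease was that of Ctsg, a serine protease of neutrophil and monocyte granules (-3.61 ± 0.39, adjusted p = 0.00181). The histone gene H2ac4 (-2.82 ± 0.69, adjusted p = 0.0289), the ferritin light chain gene Ftl1 (-2.70 ± 0.71, adjusted p = 0.0368), the mitochondrial genes Tomm5 (-2.66 ± 0.49, adjusted p = 0.0114) and Etfb (-2.64 ± 0.45, adjusted p = 0.00862), and Tfec (-2.59 ± 0.46, adjusted p = 0.00999) followed. Without Zeb2hi array 2 H2ac4 (adjusted p = 0.113), Ftl1 (adjusted p = 0.123) and Tomm5 (adjusted p = 0.0551) did not pass. Of 8 fits without 1 array, Ftl1 passed in 3, H2ac4 in 4 and Tomm5 in 6. The difference of H2ac4 was -3.43 without Zeb2hi array 1, and that of Ftl1 -3.36 without Zeb2low array 2. With the block over all arrays H2ac4 (adjusted p = 0.0575) and Ftl1 (adjusted p = 0.0834) did not pass either.

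Of 20 measured cDC1 genes, 10 were higher in Zeb2low CDPs and 0 lower (11 and 0 adjusted over the list alone). That list shifted up (list adjusted p = 6.09e-08, adjusted p = 0.138 with an estimated correlation). Among 16 antigen presentation genes 6 were higher and 2 lower (6 and 3 adjusted over the list alone), and the list shifted up (list adjusted p = 0.00553, adjusted p = 0.18 with an estimated correlation). The lower members, Psmb8 (-1.19 ± 0.19, adjusted p = 0.00631) and Psmb9 (-1.45 ± 0.40, adjusted p = 0.0431), encode immunoproteasome subunits. Psmb9 did not pass without Zeb2hi array 3 (adjusted p = 0.152) or with the block over all arrays (adjusted p = 0.0913). It passed in 3 of 8 fits without 1 array. DC maturation and migration genes had 3 of 11 members higher (3 adjusted over the list alone), with Cd86 (1.40 ± 0.22, adjusted p = 0.00656, low in Zeb2hi CDPs) and Itgax (1.11 ± 0.15, adjusted p = 0.00332) among them, and shifted up (list adjusted p = 0.00322, adjusted p = 0.138 with an estimated correlation). Plasmacytoid DC genes moved both ways, with 8 of 15 higher, such as Siglech (1.22 ± 0.26, adjusted p = 0.0176), and 2 lower, such as Atp1b1 (-1.25 ± 0.30, adjusted p = 0.026). Adjusted over the list alone the counts were 10 and 3, and the list shifted up (list adjusted p = 0.00553, adjusted p = 0.319 with an estimated correlation). Without Zeb2hi array 2 Siglech (adjusted p = 0.0784) and Atp1b1 (adjusted p = 0.0787) did not pass, nor did Atp1b1 with the block over all arrays (adjusted p = 0.063). Siglech passed in 5 and Atp1b1 in 4 of 8 fits without 1 array. Of 14 cDC2 genes 4 were higher, among them Cd7 (2.66 ± 0.33, adjusted p = 0.00284), and 2 lower (7 and 3 adjusted over the list alone). The cDC2 list did not pass (list adjusted p = 0.0535), but did without Zeb2hi array 1 (adjusted p = 0.0103), 2 (adjusted p = 0.0451) or 3 (adjusted p = 0.0388). Of 24 DC transcription factor genes 6 were higher and 2 lower (7 and 2 adjusted over the list alone), with Bcl6 (1.69 ± 0.25, adjusted p = 0.00564) and Runx1 (-1.19 ± 0.15, adjusted p = 0.0029) beside those above.

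All 20 ribosome biogenesis genes had negative differences between Zeb2low and Zeb2hi CDPs and 11 passed (16 adjusted over the list alone), such as Dkc1, a subunit of box H/ACA ribonucleoproteins (-1.31 ± 0.21, adjusted p = 0.00655). That list shifted down (list adjusted p = 4.89e-07, adjusted p = 0.138 with an estimated correlation). Of 19 DNA replication genes 8 were lower (12 adjusted over the list alone), such as Gins2 (-1.20 ± 0.27, adjusted p = 0.0217) and Mcm3 (-0.94 ± 0.21, adjusted p = 0.0209), and the list shifted down (list adjusted p = 0.000631, adjusted p = 0.257 with an estimated correlation). Without Zeb2hi array 2 Gins2 (adjusted p = 0.0918) and Mcm3 (adjusted p = 0.0911) did not pass. Of 19 mitosis genes 6 were lower (6 adjusted over the list alone), such as Birc5 (-0.80 ± 0.15, adjusted p = 0.0108), with a shift down (list adjusted p = 0.0105, adjusted p = 0.352 with an estimated correlation). Of 19 stem and progenitor genes 4 were lower, such as Meis1 (-0.84 ± 0.14, adjusted p = 0.00756), and 1 was higher, Ctla2a (1.46 ± 0.38, adjusted p = 0.0344), with 5 and 1 adjusted over the list alone. Ctla2a had a low signal in Zeb2hi CDPs and did not pass without Zeb2hi array 3 (adjusted p = 0.12). It passed in 3 of 8 fits without 1 array. The stem and progenitor list did not pass (list adjusted p = 0.0535), but shifted down without Zeb2hi array 1 (adjusted p = 0.0178), Zeb2low array 2 (adjusted p = 0.0236) or 3 (adjusted p = 0.0167). Interferon-stimulated genes had 3 of 14 members higher (3 adjusted over the list alone), such as Zbp1 (adjusted p = 0.00655) and Irf7 (1.17 ± 0.25, adjusted p = 0.0176), and shifted up (list adjusted p = 0.00448, adjusted p = 0.3 with an estimated correlation). Irf7 did not pass without Zeb2hi array 2 (adjusted p = 0.0691) and passed in 4 of 8 fits without 1 array. Of 17 immediate early and stress genes 0 passed (0 adjusted over the list alone), with Zfp36 (0.61 ± 0.22, adjusted p = 0.0913) and Ier2 (-0.78 ± 0.56, adjusted p = 0.347) as examples. Both passed with the block over the CDP arrays (adjusted p = 0.029 and adjusted p = 0.0205), and Zfp36 without Zeb2low array 1 (adjusted p = 0.0352). Their list passed without Zeb2hi array 3 (adjusted p = 0.0155) or Zeb2low array 1 (adjusted p = 0.0124), against a list adjusted p = 0.403 with all arrays.

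Markers of other cell types differed between the same groups. Of 9 T, NK and innate lymphoid cell genes 4 were higher in Zeb2low CDPs (6 adjusted over the list alone), such as Thy1 (2.22 ± 0.14, adjusted p = 0.00018), and the list shifted up (list adjusted p = 0.000208, adjusted p = 0.132 with an estimated correlation). Of 11 B cell genes 3 were higher, such as Cd22 (2.18 ± 0.27, adjusted p = 0.0029), and 1 was lower, Cd79b (-1.06 ± 0.17, adjusted p = 0.00683), with 3 and 1 adjusted over the list alone. The B cell list shifted up (list adjusted p = 0.0113, adjusted p = 0.138 with an estimated correlation). Of 20 granulocyte genes 4 were higher, such as Cebpe (1.44 ± 0.30, adjusted p = 0.017), and the protease genes Ctsg and Prtn3 (-2.23 ± 0.34, adjusted p = 0.00579) were lower (6 and 3 adjusted over the list alone). Cebpe did not pass without Zeb2hi array 2 (adjusted p = 0.0604). The granulocyte list did not pass (list adjusted p = 0.151), but did without Zeb2hi array 2 (adjusted p = 0.0466) or Zeb2low array 1 (adjusted p = 0.0126). Of 8 mast cell, basophil and eosinophil genes 2 were higher (2 adjusted over the list alone), Cpa3 (1.47 ± 0.39, adjusted p = 0.0378) and Fcer1a (1.03 ± 0.27, adjusted p = 0.0368), and the list shifted up (list adjusted p = 0.00652, adjusted p = 0.294 with an estimated correlation). Both had low signals in Zeb2hi CDPs. Cpa3 did not pass without Zeb2hi array 2 (adjusted p = 0.13), nor Fcer1a without Zeb2hi array 3 (adjusted p = 0.136). Of 8 erythroid and megakaryocyte genes 0 passed singly (0 adjusted over the list alone), with Itga2b (0.44 ± 0.14, adjusted p = 0.065) as an example, while the list shifted up (list adjusted p = 0.00739, adjusted p = 0.139 with an estimated correlation). Of 19 monocyte and macrophage genes 2 were higher, Itgam (2.31 ± 0.56, adjusted p = 0.027) and Clec4a3 (1.14 ± 0.29, adjusted p = 0.0311), and 1 was lower, F13a1 (-2.47 ± 0.47, adjusted p = 0.0128), with 3 and 2 adjusted over the list alone. Itgam did not pass without Zeb2hi array 3 (adjusted p = 0.101), nor Clec4a3 (adjusted p = 0.114) and F13a1 (adjusted p = 0.0537) without Zeb2hi array 2. Of 8 fits without 1 array, Itgam, Clec4a3 and Cpa3 passed in 3 each, Fcer1a and Cebpe in 4 each and F13a1 in 6. The monocyte list did not pass (list adjusted p = 0.0756), but did without Zeb2hi array 1 (adjusted p = 0.0269) or Zeb2low array 1 (adjusted p = 0.0211). The block over all arrays ended the calls of Itgam (adjusted p = 0.0622) and Fcer1a (adjusted p = 0.0776). With the block over the CDP arrays alone Itga2b passed (adjusted p = 0.0345), and the cDC2 (adjusted p = 0.0499), monocyte (adjusted p = 0.0489), granulocyte (adjusted p = 0.0464) and stem cell lists (adjusted p = 0.0449) passed.

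Other settings changed the calls of these lists between Zeb2low and Zeb2hi CDPs, of which the neutrophil score and the joint omission of arrays were added after seeing the data. Without a filter on low signal the stem and progenitor (adjusted p = 0.0346) list shifted down. Under the stricter filter the erythroid (adjusted p = 0.0674), B cell (adjusted p = 0.234) and mitosis (adjusted p = 0.0965) lists did not pass and the cDC2 (adjusted p = 0.0223) and monocyte (adjusted p = 0.0207) lists shifted up. After quantile normalization the B cell (adjusted p = 0.0528) and mitosis (adjusted p = 0.487) lists did not pass and the cDC2 (adjusted p = 0.0373) and monocyte (adjusted p = 0.0232) lists shifted up. Centred on array medians the cDC2 (adjusted p = 0.0122), monocyte (adjusted p = 0.0191) and granulocyte (adjusted p = 0.0219) lists shifted up. Given array weights the cDC2 (adjusted p = 0.0324) and monocyte (adjusted p = 0.0202) lists shifted up. By fry the plasmacytoid DC (adjusted p = 0.0531), mast cell (adjusted p = 0.0787), mitosis (adjusted p = 0.0575) and interferon (adjusted p = 0.0603) lists did not pass and the cDC2 (adjusted p = 0.0185) list shifted up. With a score of mature neutrophil genes as a covariate the plasmacytoid DC (adjusted p = 0.173), mast cell (adjusted p = 0.269), erythroid (adjusted p = 0.0639), antigen presentation (adjusted p = 0.0795), DC maturation (adjusted p = 0.0958), mitosis (adjusted p = 0.316) and interferon (adjusted p = 0.611) lists did not pass and the stem and progenitor (adjusted p = 0.0176) list shifted down. When Zeb2low array 1 and pre-CD8 DC array 1 were both left out the monocyte (adjusted p = 0.0149), granulocyte (adjusted p = 0.0125) and immediate early (adjusted p = 0.0149) lists shifted up.

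In total 601 of 13356 genes tested were higher and 1377 lower in Zeb2low CDPs than in Zeb2hi CDPs, of which 253 and 559 differed at least 2-fold. Higher genes made up 30.4% of the calls. That share was 40.9% when the arrays were quantile normalized again and 14.2% when each was centred on its median (371 and 2233 calls), which moved the median difference of all genes from 0.03 to -0.14. Blocked by replicate number, 422 genes were higher and 1130 lower over all arrays, against 1536 and 2534 over the CDP arrays alone. Array weights gave 1798 and 2669. The counts were 168 and 364 without Zeb2hi array 2, 171 and 407 without Zeb2hi array 3, 294 and 763 without Zeb2low array 2, and 259 and 763 without Zeb2low array 3.

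**Figure D2:**
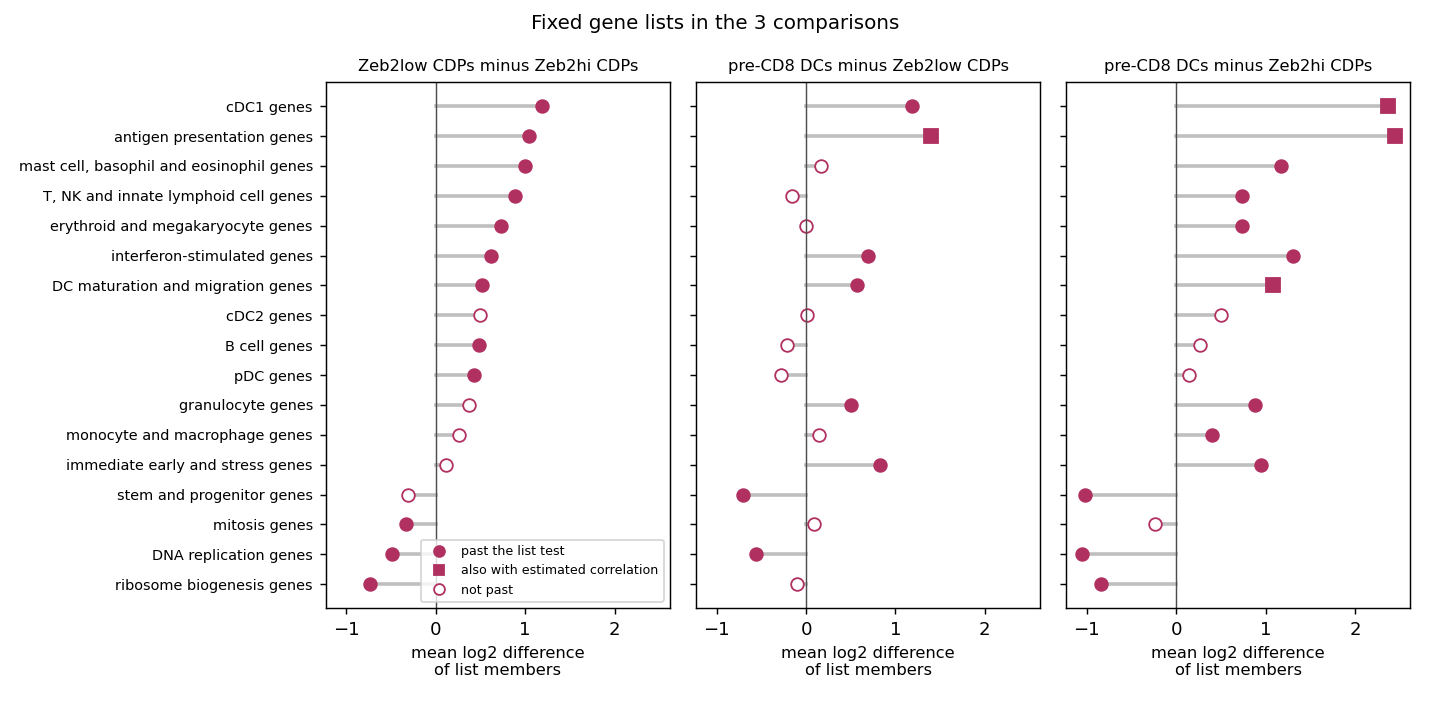
Mean log2 difference of the measured members (horizontal axis) of 17 gene lists (vertical axis) in the 3 comparisons. Filled markers passed camera with its preset correlation, squares also with an estimated correlation, and open circles did not pass.

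H2-Eb1 and Anpep were among the largest single increases from Zeb2low CDPs to pre-CD8 DCs (3 and 2 arrays, log2 differences ± SE). The MHC class II gene H2-Eb1 rose 9.17-fold (3.20 ± 0.22, adjusted p = 0.00134), Anpep, the aminopeptidase CD13, by 2.42 ± 0.18, adjusted p = 0.00134, and Naaa, an acid amidase, by 2.32 ± 0.21, adjusted p = 0.00296. Gpr141b (3.27 ± 0.56, adjusted p = 0.0478), Rtl8c (2.71 ± 0.33, adjusted p = 0.014), Gcsam (2.44 ± 0.34, adjusted p = 0.0219) and Slfn5 (2.39 ± 0.26, adjusted p = 0.00725) were the other large increases. Ccnd2, a D-type cyclin, was lower in pre-CD8 DCs (-2.06 ± 0.17, adjusted p = 0.00267). So were the glutamate receptor gene Gria3 (-2.83 ± 0.33, adjusted p = 0.0104), I730030J21Rik (-2.69 ± 0.29, adjusted p = 0.00713), Upk1b (-2.58 ± 0.28, adjusted p = 0.00732) and Il12a (-2.05 ± 0.30, adjusted p = 0.0278). Signals were low for Gpr141b in Zeb2low CDPs and for Upk1b in pre-CD8 DCs, so that their differences may be understated. Gpr141b did not pass without any 1 of the 6 CDP arrays (adjusted p from 0.086 to 0.166) and was below the signal filter without either pre-CD8 DC array. Without Zeb2low array 3 Rtl8c (adjusted p = 0.07) and Gcsam (adjusted p = 0.103) did not pass. The log2 differences of Rtl8c and Gcsam were 2.05 and 1.83 without pre-CD8 DC array 1, and 3.36 and 3.05 without array 2. Without pre-CD8 DC array 1 Slfn5 (adjusted p = 0.068), Gria3 (adjusted p = 0.083), I730030J21Rik (adjusted p = 0.0648) and Il12a (adjusted p = 0.162) did not, and Il12a passed in 2 of 8 fits without 1 array.

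Of 16 antigen presentation genes 6 were higher in pre-CD8 DCs than in Zeb2low CDPs and 0 lower (14 and 0 adjusted over the list alone). The list passed with both correlations (list adjusted p = 1.54e-17, adjusted p = 0.0213 with an estimated correlation). H2-Aa (2.30 ± 0.33, adjusted p = 0.0266) and Cd74 (2.20 ± 0.37, adjusted p = 0.0472) were among the 6, and without pre-CD8 DC array 1 neither passed (adjusted p = 0.192 and adjusted p = 0.255). They passed in 3 and 1 of the 8 fits without 1 array. Of 20 cDC1 genes 5 were higher and 0 lower (13 and 1 adjusted over the list alone), such as Gcsam and Cd36 (2.27 ± 0.35, adjusted p = 0.0334, low in Zeb2low CDPs), and the list shifted up (list adjusted p = 1.66e-16, adjusted p = 0.0636 with an estimated correlation). Cd36 did not pass without any 1 of the 6 CDP arrays (adjusted p from 0.0566 to 0.111) and was below the signal filter without either pre-CD8 DC array. DC maturation and migration genes had 2 of 11 higher, Cd83 (1.86 ± 0.29, adjusted p = 0.0338) and Cd86 (1.53 ± 0.25, adjusted p = 0.0393), with 3 higher and 1 lower adjusted over the list alone. Their list shifted up (list adjusted p = 0.00128, adjusted p = 0.0848 with an estimated correlation). Neither gene passed without pre-CD8 DC array 1 (adjusted p = 0.22 and adjusted p = 0.182), and each passed in 1 of the 8 fits without 1 array.

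Of 19 DNA replication genes 0 passed singly by limma, such as Cdc6 (-0.94 ± 0.20, adjusted p = 0.0936), but 12 were lower adjusted over the list alone and the list shifted down (list adjusted p = 5.98e-09, adjusted p = 0.151 with an estimated correlation). Of 19 stem and progenitor genes 1 was lower, Egfl7 (-1.23 ± 0.18, adjusted p = 0.0266), with 7 adjusted over the list alone and a shift down (list adjusted p = 1.25e-05, adjusted p = 0.511 with an estimated correlation). Egfl7 did not pass without pre-CD8 DC array 1 (adjusted p = 0.183) and passed in 2 of 8 fits without 1 array. Of 14 interferon-stimulated genes 0 passed singly, such as Mx1 (0.83 ± 0.15, adjusted p = 0.0618), with 7 higher adjusted over the list alone and a shift up (list adjusted p = 4.17e-07, adjusted p = 0.179 with an estimated correlation). Of 17 immediate early and stress genes 0 passed (0 adjusted over the list alone), such as Atf3 (2.13 ± 0.70, adjusted p = 0.248), and the list shifted up (list adjusted p = 3.63e-05, adjusted p = 0.569 with an estimated correlation). The granulocyte list shifted up (list adjusted p = 0.0252, adjusted p = 0.676 with an estimated correlation) with 0 of 20 members past the test (0 adjusted over the list alone). It turned down without pre-CD8 DC array 1 (adjusted p = 0.766), and without Zeb2low array 1 it did not pass (adjusted p = 0.666). Among 15 plasmacytoid DC genes 1 was lower, Cox6a2 (-1.98 ± 0.27, adjusted p = 0.0219), with 2 higher and 3 lower adjusted over the list alone. Cox6a2 did not pass without pre-CD8 DC array 1 (adjusted p = 0.148). The plasmacytoid list did not pass (list adjusted p = 0.101), but shifted down without pre-CD8 DC array 1 (adjusted p = 0.0197) or Zeb2low array 1 (adjusted p = 0.00145).

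The remaining lists did not pass between pre-CD8 DCs and Zeb2low CDPs, and 0 of their members did. These were the cDC2 (list adjusted p = 0.818, 3 higher and 3 lower adjusted over the list alone), monocyte and macrophage (list adjusted p = 0.279), mast cell, basophil and eosinophil (list adjusted p = 0.428), and erythroid and megakaryocyte genes (list adjusted p = 0.648). The B cell (list adjusted p = 0.553), T, NK and innate lymphoid cell (list adjusted p = 0.326), mitosis (list adjusted p = 0.178) and ribosome biogenesis genes (list adjusted p = 0.344) did not pass either. The mitosis list shifted up without pre-CD8 DC array 1 (adjusted p = 0.00157), the monocyte list without pre-CD8 DC array 2 (adjusted p = 0.0103) and the mast cell list without Zeb2low array 3 (adjusted p = 0.0434). The mean (0.01) and median (-0.12) of the erythroid genes differed in sign. Of 24 DC transcription factor genes 0 passed by limma (6 higher and 2 lower adjusted over the list alone).

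The same settings changed list calls between pre-CD8 DCs and Zeb2low CDPs. Under the stricter filter the granulocyte (adjusted p = 0.0529) list did not pass and the plasmacytoid DC (adjusted p = 0.0321) list shifted down. After quantile normalization the granulocyte (adjusted p = 0.0577) list did not pass. Centred on array medians the granulocyte (adjusted p = 0.0996) list did not pass. Given array weights the granulocyte (adjusted p = 0.24) list did not pass and the plasmacytoid DC (adjusted p = 0.0109) list shifted down. By fry the granulocyte (adjusted p = 0.603), stem and progenitor (adjusted p = 0.118), interferon (adjusted p = 0.0957) and immediate early (adjusted p = 0.392) lists did not pass. With a score of mature neutrophil genes as a covariate the granulocyte (adjusted p = 0.158) list did not pass and the plasmacytoid DC (adjusted p = 0.0486) list shifted down. When Zeb2low array 1 and pre-CD8 DC array 1 were both left out the immediate early (adjusted p = 0.22) list did not pass and the mitosis (adjusted p = 0.000319) list shifted up and the plasmacytoid DC (adjusted p = 0.000579), monocyte (adjusted p = 0.0415), granulocyte (adjusted p = 0.00501), mast cell (adjusted p = 0.0274) and T and NK cell (adjusted p = 0.0415) lists shifted down.

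In total 45 genes were higher and 29 lower in pre-CD8 DCs than in Zeb2low CDPs, against 1762 at an unadjusted p under 0.05. Of these, 45 and 28 differed at least 2-fold. Higher genes made up 60.8% of the calls, and 72.3% with each array centred on its median. The counts were 13 higher and 3 lower with the compared groups alone in the fit, and 10 and 5 with the replicate block over all arrays. They were 14 and 6 without pre-CD8 DC array 1, 69 and 48 without pre-CD8 DC array 2, 23 and 10 without Zeb2low array 2, and 17 and 4 without Zeb2low array 3. Leaving out a Zeb2hi array, which enters through the shared spread, gave 18 lower without array 1, 18 higher and 7 lower without array 2, and 28 and 9 without array 3. With the mature neutrophil score as a covariate 68 were higher and 49 lower.

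Antigen presentation and cDC1 genes were among the largest single increases in pre-CD8 DCs over Zeb2hi CDPs (2 and 3 arrays, log2 differences ± SE). H2-Aa was 223-fold higher (7.80 ± 0.33, adjusted p = 7.54e-06), with Cd74 (7.08 ± 0.37, adjusted p = 2.71e-05), Ifi205 (5.90 ± 0.19, adjusted p = 1.96e-06), H2-Ab1 (5.86 ± 0.28, adjusted p = 1.39e-05), H2-Eb1 (5.56 ± 0.22, adjusted p = 5.23e-06) and Tlr3 (5.28 ± 0.15, adjusted p = 1.61e-06, low in Zeb2hi CDPs) next. The largest decreases were those of Gria3 (-3.84 ± 0.33, adjusted p = 0.000306) and F13a1, a coagulation factor subunit expressed by monocytes (-3.79 ± 0.53, adjusted p = 0.00264). Cd34, a marker of progenitors (-3.59 ± 0.49, adjusted p = 0.00246), Igfbp4 (-3.26 ± 0.48, adjusted p = 0.00316), Cd93 (-3.06 ± 0.18, adjusted p = 5.08e-05) and the serine synthesis gene Phgdh (-2.94 ± 0.57, adjusted p = 0.00975) followed. The differences of F13a1 and Phgdh were -4.96 and -3.80 without pre-CD8 DC array 1, and -2.63 and -2.09 without array 2.

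Of 20 cDC1 genes 17 were higher in pre-CD8 DCs than in Zeb2hi CDPs (18 adjusted over the list alone), and of 16 antigen presentation genes 10 (10 adjusted over the list alone). Of 11 DC maturation and migration genes 5 were higher (7 adjusted over the list alone), such as Cd86 (2.92 ± 0.25, adjusted p = 0.000283) and Cd83 (2.24 ± 0.29, adjusted p = 0.002), both low in Zeb2hi CDPs. All 3 lists passed with both correlations, the cDC1 (list adjusted p = 6.28e-18, adjusted p = 0.0394 with an estimated correlation), antigen presentation (list adjusted p = 2.59e-10, adjusted p = 0.0394 with an estimated correlation) and maturation genes (list adjusted p = 7.4e-05, adjusted p = 0.0394 with an estimated correlation). DNA replication genes had 14 of 19 lower (18 adjusted over the list alone), such as Mcm6 (-1.63 ± 0.20, adjusted p = 0.00153), with a shift down (list adjusted p = 7.27e-10, adjusted p = 0.101 with an estimated correlation). Ribosome biogenesis genes had 11 of 20 lower (15 adjusted over the list alone), such as Nop58 (-1.34 ± 0.21, adjusted p = 0.0044), with a shift down (list adjusted p = 9.27e-07, adjusted p = 0.114 with an estimated correlation). Stem and progenitor genes had 9 of 19 lower, such as Cd34, and 1 higher, Kit (1.02 ± 0.26, adjusted p = 0.0295), with 12 and 2 adjusted over the list alone. They shifted down (list adjusted p = 0.000199, adjusted p = 0.32 with an estimated correlation), while Kit did not pass without pre-CD8 DC array 1 (adjusted p = 0.0621) or 2 (adjusted p = 0.134). Interferon-stimulated genes had 7 of 14 higher (10 adjusted over the list alone), such as Irf7 (2.46 ± 0.28, adjusted p = 0.00107), with a shift up (list adjusted p = 1.39e-07, adjusted p = 0.114 with an estimated correlation). Of 17 immediate early and stress genes 1 was higher, Zfp36 (1.10 ± 0.24, adjusted p = 0.0169), with 1 adjusted over the list alone and a shift up (list adjusted p = 0.000512, adjusted p = 0.385 with an estimated correlation). Zfp36 did not pass without pre-CD8 DC array 1 (adjusted p = 0.0919) or Zeb2hi array 2 (adjusted p = 0.061). Of 24 DC transcription factor genes 8 were higher, such as Bcl6 (3.11 ± 0.28, adjusted p = 0.000391), and 2 lower, Runx1 (-1.43 ± 0.17, adjusted p = 0.00123) among them (9 and 3 adjusted over the list alone).

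Markers of other cells moved here as well. Of 20 granulocyte genes 5 were higher, such as Ngp (2.19 ± 0.52, adjusted p = 0.022), and 2 lower (9 and 2 adjusted over the list alone), with a shift up (list adjusted p = 0.0147, adjusted p = 0.483 with an estimated correlation). Of 19 monocyte and macrophage genes 6 were higher and 2 lower (6 and 2 adjusted over the list alone), the latter F13a1 and Csf1r (-1.75 ± 0.32, adjusted p = 0.00779), with a shift up (list adjusted p = 0.0162, adjusted p = 0.32 with an estimated correlation). Of 8 mast cell, basophil and eosinophil genes 1 was higher (5 adjusted over the list alone), Fcer1a (1.49 ± 0.30, adjusted p = 0.0121), with a shift up (list adjusted p = 0.0031, adjusted p = 0.234 with an estimated correlation). Of 8 erythroid and megakaryocyte genes 1 was higher (0 adjusted over the list alone), Itga2b (0.54 ± 0.16, adjusted p = 0.0437), with a shift up (list adjusted p = 0.0322, adjusted p = 0.206 with an estimated correlation). Without pre-CD8 DC array 1 the granulocyte (adjusted p = 0.412), monocyte (adjusted p = 0.412), mast cell (adjusted p = 0.0843) and erythroid lists (adjusted p = 0.0774) did not pass, nor did Ngp (adjusted p = 0.127) and Itga2b (adjusted p = 0.217). Fcer1a had a low signal in Zeb2hi CDPs and did not pass without pre-CD8 DC array 2 (adjusted p = 0.0621), and without Zeb2hi array 2 the erythroid list did not (adjusted p = 0.0518). Of 9 T, NK and innate lymphoid cell genes 2 were higher (3 adjusted over the list alone), such as Thy1 (1.85 ± 0.16, adjusted p = 0.000285), with a shift up (list adjusted p = 0.00141, adjusted p = 0.0731 with an estimated correlation).

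Of 11 B cell genes 4 were higher in pre-CD8 DCs than in Zeb2hi CDPs, such as Cd22 (2.60 ± 0.30, adjusted p = 0.00124), and 1 lower (4 and 1 adjusted over the list alone), and the list did not pass (list adjusted p = 0.112). Plasmacytoid DC genes had 5 of 15 higher, such as Ccr9 (2.23 ± 0.31, adjusted p = 0.00265, low in Zeb2hi CDPs), and 3 lower, such as Atp1b1 (-1.57 ± 0.33, adjusted p = 0.0141), with 6 and 5 adjusted over the list alone and no shift (list adjusted p = 0.25). Atp1b1 did not pass without pre-CD8 DC array 2 (adjusted p = 0.0732). Genes of cDC2s had 5 of 14 higher and 3 lower, such as Tmem176a (adjusted p = 0.00182), with 6 and 3 adjusted over the list alone. The cDC2 list did not pass (list adjusted p = 0.0575), but did without pre-CD8 DC array 2 (adjusted p = 0.0482) or Zeb2hi array 1 (adjusted p = 0.0125) or 3 (adjusted p = 0.0464). Mitosis genes had 2 of 19 lower (2 adjusted over the list alone), Cdk1 (-0.81 ± 0.17, adjusted p = 0.0136) and Birc5 (-0.65 ± 0.16, adjusted p = 0.0267). Neither passed without pre-CD8 DC array 1 (adjusted p = 0.078 and adjusted p = 0.13). The mitosis list did not pass (list adjusted p = 0.16), but shifted down without pre-CD8 DC array 2 (adjusted p = 0.0267).

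List calls between pre-CD8 DCs and Zeb2hi CDPs changed as follows. Without a filter on low signal the mitosis (adjusted p = 0.032) list shifted down. Under the stricter filter the erythroid (adjusted p = 0.229) list did not pass. After quantile normalization the erythroid (adjusted p = 0.0839) list did not pass. Centred on array medians the cDC2 (adjusted p = 0.0288) list shifted up. Given array weights the cDC2 (adjusted p = 0.0397) list shifted up. By fry the monocyte (adjusted p = 0.166), granulocyte (adjusted p = 0.284), mast cell (adjusted p = 0.0723) and immediate early (adjusted p = 0.19) lists did not pass and the cDC2 (adjusted p = 0.0191) and B cell (adjusted p = 0.0191) lists shifted up. With a score of mature neutrophil genes as a covariate the monocyte (adjusted p = 0.96), granulocyte (adjusted p = 0.342), mast cell (adjusted p = 0.225), erythroid (adjusted p = 0.0918), T and NK cell (adjusted p = 0.0567) and immediate early (adjusted p = 0.168) lists did not pass. When Zeb2low array 1 and pre-CD8 DC array 1 were both left out the monocyte (adjusted p = 0.458), granulocyte (adjusted p = 0.458), mast cell (adjusted p = 0.114) and erythroid (adjusted p = 0.0812) lists did not pass.

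In total 869 genes were higher and 1483 lower in pre-CD8 DCs than in Zeb2hi CDPs, with 508 and 698 at least 2-fold. The counts were 475 and 803 without pre-CD8 DC array 1, 464 and 709 without Zeb2hi array 2, and 485 and 772 without Zeb2hi array 3. With the mature neutrophil score as a covariate they were 382 and 728.

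From Zeb2hi to Zeb2low CDPs and again from Zeb2low CDPs to pre-CD8 DCs, 26 genes rose. Among them Anpep (2.63 and then 2.42), H2-Eb1 (2.37 and 3.20), H2-Aa (5.50 and 2.30) and Cd74 (4.88 and 2.20) had the largest smaller step. The genes that fell at both steps were Cd93, a receptor of early progenitors (-1.10 and -1.97), Cnn3 (-0.74 and -1.62), the survival gene Bcl2 (-0.69 and -1.52) and Arap2 (-0.58 and -1.03). Cd96, an immunoglobulin family receptor, Gm4759 and Epb41l4b (0.78 and -1.24) were highest in Zeb2low CDPs. Signals were low for Anpep in Zeb2hi CDPs and for Gm4759 in pre-CD8 DCs. By limma with adjusted p-values 0 genes were lowest in Zeb2low CDPs, from 4380 and 1762 genes at an unadjusted p under 0.05 in the 2 steps. Without pre-CD8 DC array 1 Cnn3 (adjusted p = 0.117), Bcl2 (adjusted p = 0.162), Arap2 (adjusted p = 0.182), Epb41l4b (adjusted p = 0.191) and Gm4759 (adjusted p = 0.191) did not pass at the second step. Cd96 did not without Zeb2low array 3 (adjusted p = 0.143). Of 8 fits without 1 array, Arap2 passed at that step in 0 and Gm4759 in 1, and Bcl2 and Cd96 in 2 each. At the first step Cnn3 (adjusted p = 0.112), Arap2 (adjusted p = 0.102) and Epb41l4b (adjusted p = 0.0705) did not pass without Zeb2hi array 2, Gm4759 without Zeb2hi array 3 (adjusted p = 0.12) and Bcl2 without Zeb2low array 2 (adjusted p = 0.123). Arap2 and Bcl2 passed at the first step in 2 of 8 fits without 1 array, Cnn3 in 3, Gm4759 in 4 and Epb41l4b in 5. The block over all arrays ended the first-step calls of Bcl2 (adjusted p = 0.0923), Arap2 (adjusted p = 0.0779) and Gm4759 (adjusted p = 0.0674). The rising genes were 12 without pre-CD8 DC array 1 or Zeb2hi array 3, 9 without Zeb2hi array 2 or Zeb2low array 3, 17 without Zeb2low array 1 and 13 without Zeb2low array 2. Without pre-CD8 DC array 2, 8 genes were highest and 15 lowest in Zeb2low CDPs.

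**Figure D3:**
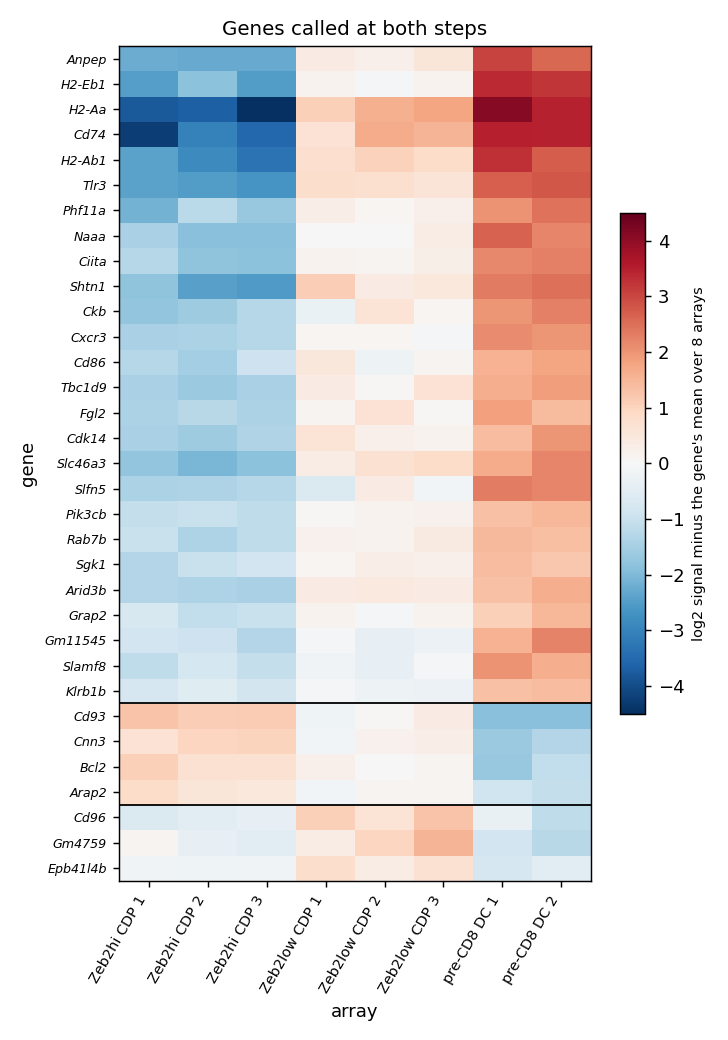
Log2 signal minus the gene's mean over the 8 arrays (colour scale) for the genes called at both steps (vertical axis), in each array (horizontal axis). From the top, 26 genes rise at both steps, 4 fall at both and 3 are highest in Zeb2low CDPs.

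The differences of Zeb2low CDPs and of pre-CD8 DCs from Zeb2hi CDPs were correlated across 13356 genes (Pearson r = 0.813), which share the Zeb2hi arrays and are not independent replicates. Unchanged groups simulated with shared Zeb2hi arrays, with independent noise and thus without the pairing of the CDP arrays, gave a mean r of 0.448. The covariance was 0.324, against 0.027 in the simulation, a difference of 0.297. Of the 601 and 869 genes higher than in Zeb2hi CDPs 428 were shared, against 39.1 for independent lists. Of the 1377 and 1483 lower genes 854 were shared, against 152.9. The expectation for independent lists leaves out that the Zeb2hi arrays, which were not split, are shared. Part of the excess of shared genes may thus come from the shared controls. The simulated covariance, which includes them, was at most 0.0301.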

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

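Between Zeb2low and Zeb2hi CDPs the counts moved with centring on array medians (371 higher, 2233 lower), array weights (1798, 2669), a 2-fold minimum (253, 559), the block over the CDP arrays (1536, 2534) and both divergent arrays left out (936 higher). Between pre-CD8 DCs and Zeb2low CDPs they moved with the compared groups alone (13, 3), the block over all arrays (10, 5), the neutrophil covariate (68, 49) and both divergent arrays left out (21 higher). Between pre-CD8 DCs and Zeb2hi CDPs they moved with the 2-fold minimum (508, 698) and the covariate (382, 728). Only the larger changes are listed, and other settings changed the counts less. Quantile normalization gave 665 higher and 960 lower in the first comparison, and the block over all arrays 595 and 998 in the third. Leaving out 1 array gave 168 to 747 higher and 364 to 1475 lower in the first comparison, 14 to 69 and 4 to 48 in the second, and 464 to 1046 and 709 to 1733 in the third. Pre-CD8 DC arrays did not deviate together with the same-numbered arrays of Zeb2low (r = -0.401, -0.587) or Zeb2hi CDPs (r = -0.172, -0.313). The deviations of the 2 pre-CD8 DC arrays mirror each other, so these values cannot settle whether same-numbered arrays share a sort, which the labels do not say. In the comparisons with pre-CD8 DCs the block over all arrays kept 9 of 45 higher and 5 of 29 lower calls against Zeb2low CDPs, and 543 of 869 and 949 of 1483 against Zeb2hi CDPs. Between the CDP fractions it ended the calls of 18 named genes and changed 0 lists. Where 1 pre-CD8 DC array was left, it was assumed to vary like the others.

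Genes rising at both steps were 9 to 22 without 1 array, 7 with the block over all arrays and 14 without both divergent arrays. Falling genes were 1 to 6 without 1 array, 2 with quantile normalization, 9 with centring or array weights, 1 with the 2-fold minimum and 7 with the covariate. Genes highest in Zeb2low CDPs were 0 to 8 without 1 array, 0 with the block, 1 with centring, 5 with array weights, and 6 with the covariate or without both divergent arrays. Lowest genes were 0 to 15 without 1 array, 1 with quantile normalization, 1 with trend and robust settings and 2 with centring. The correlation of the differences was 0.690 to 0.846 without 1 array.

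With an estimated correlation 0, 1 and 3 lists shifted in the 3 comparisons in the order above, fry shifted 4 in the second, and with the covariate 6 passed in the first (5 of the 12, and the stem and progenitor list) and 7 in the third. The granulocyte list of the second comparison lay between 0.000341 and 0.766 without 1 array, and reversed at the upper end. It also reversed without both divergent arrays (adjusted p = 0.00501), as did the monocyte (0.0415) and mast cell lists (0.0274), and in the third comparison it reversed with the covariate (0.342). Over all settings the calls of named genes stayed 3504 times, weakened 546 times, strengthened 22 times and reversed 0 times. Those of lists did so 956, 76, 51 and 5 times. A change of sign counted as reversed only where at least 1 of the compared fits passed, and as stayed elsewhere. The difference of Pf4 between pre-CD8 DCs and Zeb2low CDPs, for example, went from 0.68 to -0.48 without pre-CD8 DC array 1. The cause was not tested for these changes.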

Other observations

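The 9 gene families here were chosen after the results were seen, and family p-values were adjusted over these 9 alone. They do not allow for that choice and only describe these data. At camera's preset correlation each family shifted between Zeb2low and Zeb2hi CDPs with the arrays as deposited (highest adjusted p = 0.0372, for histone genes). The family values below are those with an estimated correlation unless the preset one is named. Of 44 proteasome subunit genes 25 were lower in Zeb2low CDPs than in Zeb2hi CDPs and 0 higher (median log2 difference -0.79, camera adjusted p = 0.0308 with an estimated correlation), such as Psmb7 (-2.09 ± 0.23, adjusted p = 0.00203) and Psma1 (-1.77 ± 0.20, adjusted p = 0.00203). Of 77 mitochondrial ribosome genes 36 were lower (median -0.59, adjusted p = 0.0308 with an estimated correlation). The lower proteasome genes were 14 after quantile normalization and 35 when the arrays were centred on their medians. With an estimated correlation both families passed when the arrays were quantile normalized again (adjusted p = 0.0234 each) and not when they were centred (adjusted p = 0.0825 each). At the preset correlation both passed when centred (adjusted p = 1.14e-12 and 3.55e-12). Respiratory chain (22 of 89 lower) and cytosolic ribosome genes (9 of 53 lower) passed as deposited with an estimated correlation (adjusted p = 0.0308 each). With that correlation they passed neither after quantile normalization (adjusted p = 0.445 and 0.43) nor when centred (adjusted p = 0.0825 and 0.086). At the preset correlation both passed when centred (adjusted p = 3.15e-06 and 6.28e-06) and neither after quantile normalization (adjusted p = 0.0866 and 0.113). After quantile normalization 15 respiratory chain genes were lower and 2 higher, and of the cytosolic ribosome genes 3 were lower, against 19 when centred. Of 15 tRNA synthetase genes 9 were lower (median -0.82, adjusted p = 0.0658 with an estimated correlation). Of 28 histone genes 5 were lower (adjusted p = 0.425 with an estimated correlation), or 3 lower and 1 higher after quantile normalization.

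Of 8 Toll-like receptor genes 3 were higher in Zeb2low CDPs, Tlr3, Tlr4 (1.31 ± 0.31, adjusted p = 0.0262) and Tlr12 (0.92 ± 0.16, adjusted p = 0.0089), with a family adjusted p = 0.0546 with an estimated correlation. Tlr4 passed in 4 of 8 fits without 1 array (adjusted p = 0.102 without Zeb2hi array 2). Tlr3 and Tlr4 had low signals in Zeb2hi CDPs. In pre-CD8 DCs 4 were higher than in Zeb2hi CDPs, with Tlr9 (1.18 ± 0.18, adjusted p = 0.00349) added. There the family passed with an estimated correlation (adjusted p = 0.0269), but not when the arrays were centred (adjusted p = 0.056). At the preset correlation it passed when centred (adjusted p = 4.04e-07). The chemokine receptor gene Cxcr3 rose at both steps (1.41 ± 0.13, adjusted p = 0.000923, then 2.02 ± 0.15, adjusted p = 0.00134), while Cxcr4 was lower in Zeb2low CDPs (-0.58 ± 0.15, adjusted p = 0.0343). Cxcr4 passed in 3 of 8 fits without 1 array (adjusted p = 0.108 without Zeb2low array 2) and not with the block over all arrays (adjusted p = 0.0614). Their family of 13 had 3 higher and 1 lower there (adjusted p = 0.132 with an estimated correlation). After quantile normalization 1 was higher and 0 lower, so that Cxcr4 did not pass, and when centred 1 was higher and 1 lower. Of 9 Schlafen genes 2 were higher in Zeb2low CDPs (adjusted p = 0.0658 with an estimated correlation), Slfn5 (1.22 ± 0.23, adjusted p = 0.0118) and Slfn2 (1.31 ± 0.37, adjusted p = 0.0485), and 1 when the arrays were centred. Slfn5, with a low signal in Zeb2hi CDPs, did not pass without Zeb2hi array 2 (adjusted p = 0.0553). Slfn2 passed in 3 of 8 fits without 1 array (adjusted p = 0.151 without Zeb2hi array 3) and not with the block over all arrays (adjusted p = 0.0922).

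The regroupings of the CDP arrays were planned before the data were examined. Among the 10 splits of the 6 CDP arrays into 3 and 3, 1 gave as many higher calls and 1 as many lower calls as the real one, which was itself (601 and 1377, highest other 0 each). For the gene lists 2 splits gave 12 shifts, the real one and that of Zeb2hi array 1 with Zeb2low arrays 2 and 3, which also parts all 3 pairs. The splits that mixed the fractions shifted 2 to 12 lists, with 0 genes called in each. The number of list shifts thus did not set the real split apart. The 10 splits are too few for a share under 0.05. Each other split also mixes the fractions, so that their difference adds to its spread and few calls could be made.

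The remaining tests were chosen after the results were seen. Of 24 mature neutrophil genes 7 were higher in Zeb2low CDPs than in Zeb2hi CDPs, such as Wfdc21 and Lrg1, with a mean log2 difference of 1.84 over all 24, while the early granule genes Ctsg and Prtn3 were lower. The mean of the 24 varied within groups with an SD of 1.10, against 0.168 for the upper tail of random lists matched on signal. Genes that vary together for any reason could exceed such lists. This SD thus cannot tell carry-over from a difference between the sorted cells. The score was 11.2 and 8.84 on the pre-CD8 DC arrays, 7.59, 8.46 and 7.03 on the Zeb2hi arrays, and 8.49, 10.6 and 9.47 on the Zeb2low arrays. Neutrophil RNA carried over in differing amounts may account for these genes. With the score as a covariate 63.6% of 1971 other calls between the CDP fractions stayed, so a linear effect of the score did not account for those. Among all calls 337 of 601 higher and 918 of 1377 lower ones stayed. But every Zeb2low score lay above every Zeb2hi score, so score and fraction are confounded and the covariate cannot exclude carry-over as a cause. Between pre-CD8 DCs and Zeb2low CDPs 74 of 74 calls stayed. The cause was likewise left open for the calls between pre-CD8 DCs and Zeb2hi CDPs (903 of 2352 stayed, with a median ratio of log2 differences of 0.966) and for the list shifts between the CDP fractions (5 of 12 stayed).

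More of the calls were lower than higher in Zeb2low CDPs (69.6%). A narrower range of values on the Zeb2low arrays could contribute, since the range between a low and a high percentile of log2 signal was 5.66, 5.93 and 5.92 on Zeb2low arrays 1, 2 and 3 and 6.12 to 6.19 on the Zeb2hi arrays. With 1 distribution for all arrays the lower share was 59.1%, and 53.4% to 62.0% without 1 array. The test left open whether the range is the whole cause.

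Pre-CD8 DCs differed from Zeb2low CDPs in 74 genes, against 1978 between the CDP fractions. Fewer pre-CD8 DC arrays could be the cause, but with 1 of the 6 CDP arrays left out 532 to 1961 genes were still called between those fractions. The same 2 arrays gave 2352 calls against Zeb2hi CDPs. The 532 calls argue against the number of arrays as the whole cause. The fit used 1 spread per gene for all groups, so both comparisons with pre-CD8 DCs had the same spread and numbers of arrays. Their median absolute log2 differences were 0.2116 from Zeb2low CDPs and 0.3158 from Zeb2hi CDPs. With the 74 and 2352 calls, this argues against the spread within groups as the whole cause. The spread may still contribute. The median absolute difference between the 2 pre-CD8 DC arrays (0.2826) exceeded those of array 2 from Zeb2low arrays 2 (0.2025) and 3 (0.2064).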
